A study of Rattus norvegicus with 9 samples.

How the data were processed

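The series holds 9 arrays of hypothalamus from male rats aged 13 weeks, 1 array per rat. Per the labels and the series description, 4 rats ate a medium-fat diet with instant noodles and their seasonings. The other 5 rats ate that diet with the seasonings left out. The treatment text of the labels is the same for both groups, and the difference in seasonings comes from the series description. Group and rat number were taken from each sample's title. The labels give the feeding period as 30 days in one place and as 4 weeks in another, and state that food intake was matched between the diets at about 60 g per kg body weight per day. Noodles made up 30% of the diet by weight and fat gave 26% of its energy. The rats' strain, the time of day at dissection and the order of hybridization are not given in the sources used here.

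Total RNA was extracted with TRIzol and cleaned on a column, and biotin-labelled cRNA was made from 100 ng, per the labels' protocols. The authors deposited 1 table of log2 values, of 31099 probe sets per array, from an Affymetrix rat expression array; how the probes of a probe set were summarized and how arrays were normalized is not given in the sources used here. That the deposited values are log2 was taken from their range (5.13 to 13.7) and not from a label. The array medians lay between 6.777 and 6.785, so the values were used as deposited, with no further scaling. Pairwise correlations between arrays over all probe sets ran from 0.997 to 0.999, and none of the 36 pairs of columns was identical. The number of arrays limits the precision of every value, and the files give no signal over background for single probe sets.

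The deposited log2 values differ very little between arrays for most probe sets. Of the probe sets tested, 29759 (95.9%) ranged over less than 0.01 log2 units across the 9 rats, 1223 (3.94%) ranged over more than 0.05, and 60 lay in between. Those above 0.05 are called variable probe sets, and those under 0.01 are called compressed. A difference between diets in a compressed probe set cannot be read as a fold change of the transcript, and is given here only for its direction and its test. The limit of 0.05 was chosen after the values had been seen.

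The 57 control probe sets of the manufacturer were left out, which left 31042. The platform's annotation, matched by gene number to a table of rat genes (assembly GRCr8, used for names only), gave 1 symbol to 20826 probe sets and several symbols to 436, and 9780 were unnamed here. Of the probe sets with 1 symbol, 20758 were found in the gene table and 0 symbols changed. The named probe sets cover 14217 genes. No gene was named from a probe set with several symbols. Genes with more than 1 probe set are given by the named probe set, and further probe sets were compared only for the variable genes named and for Gnrh1.

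The diets were compared with limma (version 3.58.1 in R 4.3.3), by lmFit and eBayes with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment over the 31042 probe sets and a threshold of 0.05. Differences are noodle diet minus control, in log2 units, with the standard error of the fit. Per the labels each array is a different rat, so p-values measure the spread between these 9 animals. The text names genes by a rule fixed before the data were examined: the 12 genes of largest difference in each direction among those that pass, filled up, where fewer pass, with the genes of lowest unadjusted p whose mean lies at or above the median probe set. It also names 12 measured hypothalamic peptide genes whatever their p, and up to 4 members of each list described. Because most genes named by that rule came from compressed probe sets, the 8 variable probe sets of lowest p in each direction were added after their values had been seen.

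Before the data were examined, 35 gene lists were fixed from textbook knowledge, for feeding and hypophysiotropic peptides, hormone receptors, lipid metabolism, transmitter systems, stress, clock, mitochondria and ribosomes, cell types of the brain and its coverings, and neighbouring regions. Lists were tested with limma's camera at its preset correlation of 0.01, on 1 probe set per gene (the highest mean), with at least 5 measured genes per list and adjustment over the 35 lists. Agrp is named by 0 probe sets and was not analysed here. For each list with at least 2 variable members a score per rat was taken, the mean deviation of those members from their mean over the 9 rats, and compared between diets by an exact permutation test over all 126 ways to split the rats into 4 and 5.

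Alternatives fixed in advance were quantile normalization, a common array median, a filter on low means, no intensity trend, array weights, a floor at the 20th percentile, leaving out each rat, a robust variance model, 1 or averaged probe sets per gene, a rank product with 100 permutations, an adjusted p under 0.10, 1 surrogate variable (the iteratively reweighted algorithm of the sva package, rewritten in base R), camera with estimated correlations or on ranks, and fry. Estimated correlations were run on the values as deposited, not together with another alternative. A covariate for meningeal markers, a restriction to variable probe sets and a block on sets of consecutive rat numbers were added after seeing the data.

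Limma, the rank product and camera were tested on simulated data made from the real means and within-group spreads. The permutation tests, fry, estimated correlations and the surrogate variable were not. In a simulation of this comparison over 31042 probe sets, limma called 31 of 50 probe sets shifted by 4 within-group SD and 47 of 50 shifted by 6, with 9 false calls among 30842 unchanged. Among variable probe sets it called 15 of 50 shifted by 0.5 log2 units, 40 of 50 shifted by 1 and 49 of 50 shifted by 2. The rank product called 48 of 50 of those shifted by 0.5. Calls among variable probe sets were counted whatever their direction. With no probe set changed, limma made 0 calls and the rank product 470, so the 48 of 50 does not measure its sensitivity. Camera, over 14217 genes, called a list shifted by 1 within-group SD in 20 of 20 simulations and 0 of 680 unshifted lists. The simulated noise was independent between probe sets, while members of real lists can correlate. These counts therefore do not give camera's error rates on the real values, where other splits of the rats gave up to 13 lists. Figures were drawn with matplotlib 3.10.9.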

Results

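Expression in the hypothalamus was measured in 9 male rats, 4 fed a noodle diet with seasonings and 5 fed the same diet without them, to ask whether seasonings alter hypothalamic transcripts. The hypothalamus holds the neurons that set feeding, water balance and pituitary output. Values are means ± SD of deposited log2 values, with 4 noodle-diet and 5 control rats throughout.

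Most deposited values hardly moved between animals. The median probe set ranged over 0.000518 log2 units across the 9 rats, while the 1223 variable probe sets had a median SD of 0.154 and 140 probe sets ranged over more than 1 log2 unit. The variable probe sets included those of the peptide genes Pmch, Avp and Oxt and of the myelin gene Mbp.

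**Figure D1:**
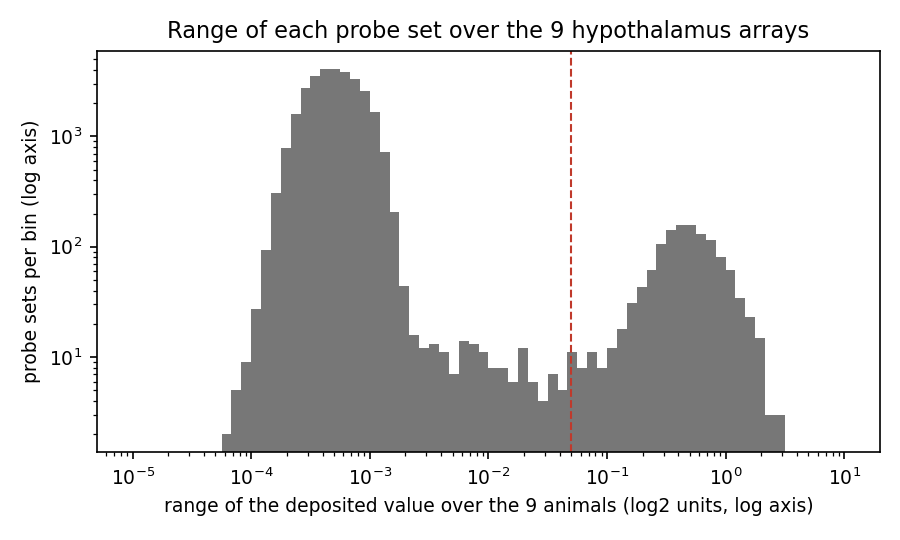
Range of each of 31042 probe sets over the 9 rats (log2 units, log axis) against the number of probe sets per bin (log axis). The distribution has separate humps, with 29759 probe sets under 0.01 and 1223 above the dashed line at 0.05.

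Comparing the diets, no gene passed limma's test after correction, and the leading differences were small. Sec62, a part of the protein translocation machinery of the endoplasmic reticulum, measured 10.01 ± 0.061 on the noodle diet and 9.90 ± 0.038 on the control diet, a difference of 0.11 (SE 0.031), with 4 of 4 noodle-diet rats above every control. Mrpl50, a protein of the large mitochondrial ribosomal subunit, measured 7.41 ± 0.092 against 7.04 ± 0.21 (difference 0.37, SE 0.11), and Mrpl22, of that same subunit, 8.14 ± 0.15 against 8.44 ± 0.12 (difference -0.29, SE 0.085). These probe sets kept their directions in the alternative limma fits that hold them, without passing. The fit on the probe set of highest mean per gene replaces those of Sec62 and Mrpl50 by compressed ones, of which that of Sec62 stood at -1.8e-05.

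By limma, 0 of 31042 probe sets had an adjusted p under 0.05, and the smallest adjusted p rounded to 1. At an unadjusted p under 0.05 there were 712 probe sets, 293 higher and 419 lower on the noodle diet, where chance alone gives 1552. The rank product, a test on ranks of pairwise differences, called 190 probe sets, but it also called 470 in simulated data with no change, where limma called 0. Among the 1223 variable probe sets, 11 had an unadjusted p under 0.05, where chance gives 61, and only Sec62 had groups that did not overlap. Over all probe sets 176 had groups that did not overlap (0.567%), against 1.59% by chance.

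The named genes with the lowest unadjusted p on the higher side were Zfp90, Palmd, Pacs1, Cmc1, Lrrc57, Sorl1, Npas2, Kat6b, Sec62, Ptprm, Proser1 and Mrpl50. Those on the lower side were Wipf3, Atg14, Gga3, Ncstn, Dimt1, Dhdds, Myo16, Aasdh, Xrn1, Arhgap33, Mkks and Mrpl22. None passed by limma, and the rank product called 3 of these 24, Sec62, Mrpl50 and Mrpl22. Sorl1 is a neuronal sorting receptor, Npas2 a clock transcription factor, Ncstn the nicastrin subunit of gamma-secretase, Atg14 an autophagy factor and Xrn1 a cytoplasmic exoribonuclease. Apart from Sec62, Mrpl50 and Mrpl22, all of these came from compressed probe sets. There the differences ran from 0.00018 (Sorl1) to 0.00054 (Palmd) on the higher side and from -0.00079 (Wipf3) to -0.00011 (Xrn1) on the lower side. Pacs1, Lrrc57, Sorl1, Npas2 and Proser1 pointed the other way after quantile normalization.

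Among variable probe sets, picked after their values were seen, the higher ones also included Mfap3 (7.05 ± 0.22 against 6.63 ± 0.25), Slc14a1, a urea transporter (7.63 ± 0.19 against 7.40 ± 0.15), and Frzb, a secreted Wnt antagonist (6.90 ± 0.12 against 6.68 ± 0.17). Tmem144, Phc3 and the chemokine gene Cxcl12 differed by 0.15, 0.12 and 0.10. The lower ones included Rdh12, a retinol dehydrogenase (6.06 ± 0.31 against 6.39 ± 0.24), C1qa, a complement chain made by microglia (8.47 ± 0.17 against 8.73 ± 0.16), and Dbp, a clock-controlled transcription factor (8.80 ± 0.15 against 8.95 ± 0.053). Cdhr4, Slx4ip, Tmem119 and Cfap144 differed by -0.18, -0.17, -0.17 and -0.14, and Tmem119 ran from -0.21 to -0.10 with single rats left out. None of the 16 variable genes named passed by limma, while the rank product called 16 of them. Those calls add no support, since the genes were picked by low p in these same values. Further probe sets of Sec62, Mrpl50, Tmem144, Mfap3, Frzb, Slc14a1 and Phc3 were compressed and could not show a difference of this size. Among further probe sets that were variable, Cfap144 stood at -0.15, near its first, and Cxcl12 at -0.011.

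Among peptides that drive or curb food intake, Hcrt, Pmch, Npy and Cartpt differed between diets by less than the SD of either group. The appetite-raising genes Hcrt (orexin), Pmch (melanin-concentrating hormone) and Npy measured 9.81 ± 0.18 against 9.65 ± 0.53, 12.20 ± 0.095 against 12.13 ± 0.20, and 8.80 ± 0.12 against 8.83 ± 0.053. The appetite-curbing Cartpt measured 10.75 ± 0.16 against 10.78 ± 0.040, and Nmu (neuromedin U) 7.80 ± 0.42 against 7.32 ± 0.66. The 95% interval of the difference was -0.16 to 0.099 for Npy, -0.19 to 0.14 for Cartpt and -0.18 to 0.31 for Pmch, but -0.47 to 0.77 for Hcrt, so larger orexin differences were not excluded. The Pomc, Crh and Ghrh probe sets were compressed, with differences of 9.8e-05, -0.00011 and 6.8e-05, and Ghrh turned to -0.00012 after quantile normalization. With single rats left out Pomc ran from 5.2e-05 to 0.00015 and Crh from -0.00018 to -2.6e-05. By camera neither the 8 measured orexigenic genes (4 higher) nor the 14 anorexigenic genes (5 higher) passed, with an adjusted p of 0.867 for both.

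Hormones of water balance and of the pituitary axis varied more between rats than between diets. Avp (vasopressin) measured 11.44 ± 0.64 against 11.28 ± 0.34 and Oxt (oxytocin) 9.93 ± 0.85 against 9.91 ± 0.55. Trh measured 8.75 ± 0.27 against 8.89 ± 0.097, Sst 9.71 ± 0.062 against 9.83 ± 0.15 and Gnrh1 6.34 ± 0.36 against 6.27 ± 0.18. A second Gnrh1 probe set was compressed. The direction of Npy, Cartpt, Hcrt, Pmch, Oxt and Gnrh1 depended on single rats. Without noodle-diet rat 7 the differences of Npy, Cartpt, Oxt and Gnrh1 became 0.0064, 0.052, -0.18 and -0.085, and without control rat 2 those of Hcrt, Pmch and Oxt became -0.074, -0.0075 and -0.095. Oxt also turned negative without noodle-diet rats 4 (-0.076) or 13 (-0.11) and without control rats 5 (-0.11) or 11 (-0.030). With single rats left out Avp ran from 0.033 to 0.48, Trh from -0.22 to -0.022 and Sst from -0.18 to -0.068. None of the 12 peptide genes passed by limma, while the rank product called 3, Avp, Oxt and Sst. By camera the adjusted p was 0.867 for the lists of the 9 hypophysiotropic hormones (4 higher), the 18 magnocellular and osmotic response genes (7 higher), the 13 genes of thyroid hormone handling and response (8 higher), the 16 of the growth hormone and IGF axis (7 higher) and the 25 receptors and signalling genes of metabolic hormones (9 higher). The hypophysiotropic list passed on the lower side with a common array median (adjusted p = 0.0220), and not with an estimated correlation (0.958).

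**Figure D2:**
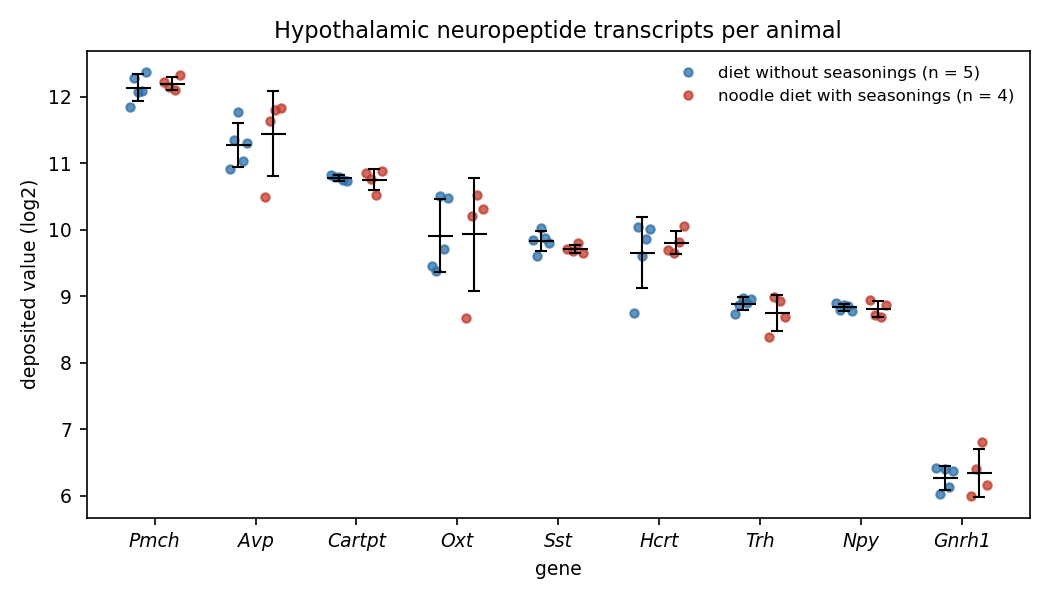
Deposited log2 value (vertical axis) of 9 neuropeptide genes in each rat; points are rats, bars are means ± SD of 5 control and 4 noodle-diet rats. The groups overlap for every gene, and noodle-diet rat 1 lies lowest for Avp at 10.49 and for Oxt at 8.66.

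Genes of lipid metabolism, the subject named in the series title, did not pass either. Of 22 genes of fatty acid synthesis and desaturation 15 were higher on the noodle diet (camera p = 0.0378, adjusted p = 0.441; p = 0.175 with an estimated correlation), and only 3 were variable. Elovl5, a fatty acid elongase, measured 9.93 ± 0.097 against 9.91 ± 0.099, and the desaturase gene Scd 7.21 ± 0.036 against 7.21 ± 0.057. In cholesterol biosynthesis 14 of 20 genes were higher (camera adjusted p = 0.707, 0.0129 with a common array median and 0.958 with an estimated correlation), with Cyp51 at 10.002 ± 0.079 against 9.938 ± 0.045 and Idi1 at 8.46 ± 0.11 against 8.41 ± 0.063. In fatty acid oxidation 16 of 25 were higher (camera adjusted p = 0.472), with Acaa2 at 7.75 ± 0.15 against 7.66 ± 0.26.

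Cell-type markers gave the lists nearest to the threshold, and none of the 35 lists passed. By camera 0 lists had an adjusted p under 0.05 and 3 had an unadjusted p under 0.05, and by fry 0 lists had either. Of 22 microglia and macrophage markers 15 were lower on the noodle diet (camera p = 0.0034, adjusted p = 0.0703; p = 0.303 with an estimated correlation). Besides C1qa, the complement genes C1qb and C1qc measured 8.05 ± 0.15 against 8.18 ± 0.13 and 7.35 ± 0.19 against 7.53 ± 0.12, and the microglial gene Tmem119 measured 6.94 ± 0.14 against 7.10 ± 0.14. The microglia list passed with quantile normalization (adjusted p = 0.0427), array weights (0.0164), a block on sets of rat numbers (0.0138), over variable probe sets alone (0.0047) and without noodle-diet rat 1 (0.00046), control rat 11 (0.0016) or control rat 14 (0.0099), while the per-rat microglia score differed by -0.089 (exact 2-sided permutation p = 0.556). Over 21 camera alternatives its adjusted p lay between 1.7e-16, with a common array median, and 0.958, with an estimated correlation. The block leaves control rat 11 without a partner and gives the same diet differences as leaving that rat out. The passes of these fits are therefore not independent.

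Of 15 astrocyte markers 11 were higher on the noodle diet (camera p = 0.0040, adjusted p = 0.0703; p = 0.0755 with an estimated correlation). Of these 15 markers 7 were variable. The members of lowest limma p, Slc1a2 and Fgfr3, came from compressed probe sets (differences 0.00032 and 0.00021). Among the variable ones, S100b measured 12.58 ± 0.16 against 12.38 ± 0.24 and the water channel gene Aqp4 11.05 ± 0.11 against 10.99 ± 0.054. Gfap measured 10.88 ± 0.21 against 10.93 ± 0.36. The astrocyte list passed with quantile normalization (adjusted p = 0.0427), with a common array median (0.0060) and without noodle-diet rat 7 (0.0229) or control rat 5 (0.0218), in a range of 0.0060 to 0.958 over 21 camera alternatives. Oligodendrocyte markers did not pass (camera adjusted p = 0.867), with Mbp at 13.10 ± 0.082 against 13.10 ± 0.18 and Mog at 9.06 ± 0.15 against 9.09 ± 0.32. That list passed on the higher side without control rat 8 (adjusted p = 0.0064) and with quantile normalization (0.0292), in a range up to 0.973 over 21 camera alternatives, and not with an estimated correlation (0.958).

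Meningeal and fibroblast markers differed widely between rats on both diets. The collagen gene Col1a2 spanned 7.590 to 9.005, Igf2 7.99 to 9.65 and Ogn 6.80 to 8.71. The score of this list was -0.0082 ± 0.45 on the noodle diet and 0.0066 ± 0.44 on the control diet (exact 2-sided permutation p = 0.960; camera adjusted p = 0.867). No list score passed, with exact permutation p from 0.103 upward over 26 lists and a smallest adjusted p of 0.984. The remaining cell and tissue types did not pass on the deposited values. Camera gave an adjusted p of 0.867 for neurons, for ependymal cells and tanycytes, for choroid plexus and for anterior pituitary, of 0.717 for erythroid cells and of 0.927 for endothelial cells and pericytes. With quantile normalization neurons (adjusted p = 0.0050) and ependymal cells (0.0105) passed on the higher side. With a common array median neurons (0.0016), ependymal cells (0.0305) and anterior pituitary (0.0028) passed on the higher side and erythroid cells (0.0016) on the lower, and with an estimated correlation none did (0.958 for the smallest). The neurofilament gene Nefm measured 9.05 ± 0.082 against 8.97 ± 0.081, Hdc (histidine decarboxylase) 8.53 ± 0.048 against 8.33 ± 0.19, the globin gene Hbb 10.87 ± 0.31 against 11.21 ± 0.40 and the thyrotropin gene Tshb 9.67 ± 0.89 against 8.86 ± 1.22. Among region markers the adjusted p was 0.490 for cortex, hippocampus and amygdala, 0.827 for striatum and 0.867 for thalamus and for the hypothalamic nuclei.

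**Figure D3:**
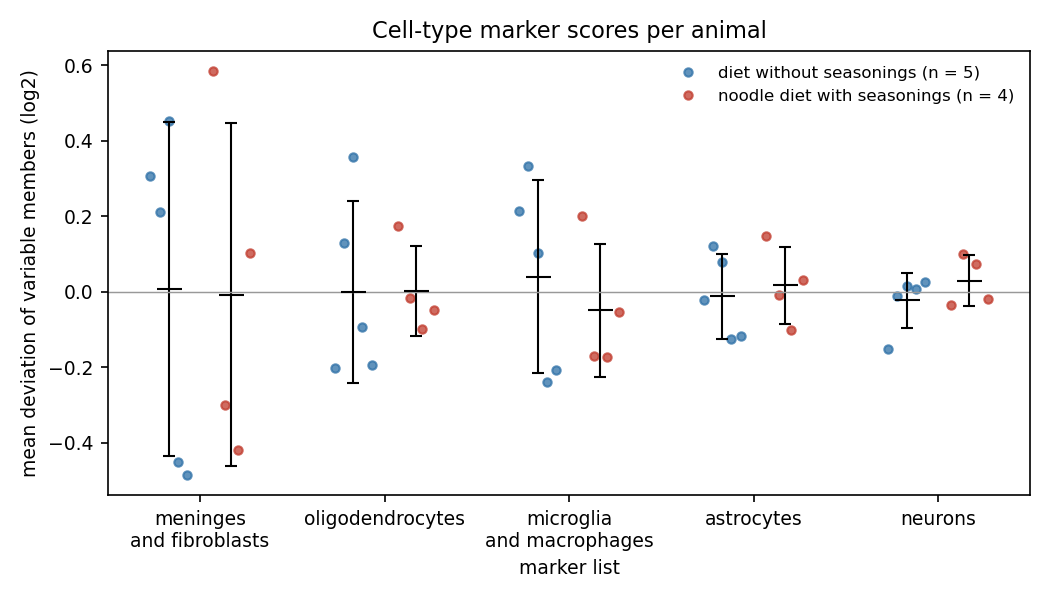
Score of 5 cell-type marker lists per rat (mean deviation of the variable members, log2 units, vertical axis); points are rats, bars are means ± SD of 5 control and 4 noodle-diet rats. Meningeal scores span -0.49 to 0.58 and occur high and low on both diets, while neuron scores span -0.15 to 0.099.

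Transmitter systems did not pass on the deposited values. Of 28 genes of glutamate receptors and transport 14 were higher (camera adjusted p = 0.867), with the receptor gene Gria3 at 8.41 ± 0.11 against 8.36 ± 0.16. The adjusted p was also 0.867 for GABA synthesis, receptors and transport, with Gad1 at 10.82 ± 0.013 against 10.83 ± 0.13, and for monoamine signalling, with Maob at 10.09 ± 0.093 against 9.98 ± 0.11. Monoamine signalling passed on the higher side with quantile normalization (adjusted p = 0.0050) and a common array median (0.00019), and not with an estimated correlation (0.958). Of 17 glucocorticoid-responsive genes 13 were lower (camera adjusted p = 0.709), among them Sgk1 at 8.19 ± 0.20 against 8.37 ± 0.22 and Klf9 at 9.31 ± 0.13 against 9.41 ± 0.17. This list passed on the lower side over variable probe sets alone (adjusted p = 0.0275) and with a common array median (6.6e-09), in a range up to 0.995 over 21 camera alternatives. With an estimated correlation it did not pass (adjusted p = 0.958), and its per-rat score gave an exact 2-sided permutation p of 0.516. The adjusted p was 0.867 for immediate early genes, for inflammatory cytokines and the NF-kB pathway, for endoplasmic reticulum stress, for oxidative phosphorylation and for cytosolic ribosomal proteins, and 0.717 for heat shock proteins. Ribosomal protein genes passed on the lower side without noodle-diet rat 1 (adjusted p = 0.0102). With quantile normalization they passed as higher relative to other genes (0.0497), although their median difference was -0.00019. With an estimated correlation they did not pass (0.958). The immediate early gene Egr1 measured 8.24 ± 0.21 against 8.38 ± 0.27.

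Of 18 circadian clock genes 11 were lower (camera adjusted p = 0.867). Npas2 was the member of lowest p, and its adjusted p over the list alone was 0.0927. Over the 35 lists, 0 members passed when adjusted over the list alone, and 0 passed over all probe sets. Of the 3 lists with an unadjusted camera p under 0.05, 0 kept it with an estimated correlation. The median difference was negative although camera pointed up for neurons, GABA, oxidative phosphorylation, anterior pituitary, thalamus, choroid plexus, hypothalamic nuclei and meninges. The mean difference had the other sign than camera and the median for the hypophysiotropic, anorexigenic and magnocellular lists, and for endothelial cells. In 9 of the 35 lists at most 1 member was variable, so for those the test rests on compressed values. Camera counts compressed and variable members alike, so it rests largely on compressed values in other lists too. Variable members were 2 of 71 for oxidative phosphorylation, 4 of 42 for ribosomal proteins and 7 of 15 for astrocytes. For meninges 15 of 15 were variable, and for oligodendrocytes 15 of 16.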

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

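The outlying samples came from a rule fixed in advance, and the test of the clock genes was chosen after their values had been seen. In 150 groups tested (2 diets for each named gene and list score), 16 had 1 rat far from the others of its diet, where chance gives about 8.

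In noodle-diet rat 1, Avp stood at 10.49, with the other 3 rats of its diet at 11.64 to 11.84, and Oxt at 8.66, with the others at 10.21 to 10.52. The score of magnocellular and osmotic response genes, which holds both, was -0.309 there and 0.093 to 0.16 in the others. In the same rat the score of fatty acid synthesis and desaturation was 0.090, against -0.035 to -0.018. That rat also had the highest meningeal score (0.584), which Elovl5 and Elovl1 of this list followed over the rats.

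Control rat 2 stood apart for Mrpl50 at 7.39 (others 6.88 to 7.03), which lies at the level of the noodle diet, for Cxcl12 at 7.81 (others 7.91 to 7.95), for the neuron score at -0.151 (others -0.012 to 0.025) and for Cmc1, a compressed probe set, at 7.4576 (others 7.4579 to 7.4580). Control rat 11 stood apart for Frzb at 6.98 (others 6.57 to 6.63), and, by less than 0.001 log2 units, for Palmd at 6.9695 and Sorl1 at 6.9786. The GABA score was 0.233 in control rat 14 (others -0.093 to -0.022) and 0.136 in noodle-diet rat 7 (others -0.078 to -0.041). Ptprm, a compressed probe set, stood apart in noodle-diet rat 13 at 7.5674.

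Dbp stood at 9.02 in noodle-diet rat 13 and at 8.71 to 8.74 in the other 3 noodle-diet rats, with the 5 controls at 8.897 to 9.003, and the clock list score was 0.082 in that rat against -0.052 to -0.045. Of 10 clock output genes (Per, Nr1d, Dbp, Tef, Hlf and Bhlhe genes) 9 were lower on the noodle diet, and of 5 partner genes (Bmal1, Npas2, Clock, Cry1, Nfil3) 3 were higher. A candidate explanation is a different clock phase at dissection, from the diet or from the time of day at which rats were taken. Outputs minus partners, in SD units per gene, averaged -0.47 ± 1.15 on the noodle diet and 0.37 ± 0.47 on the control diet (exact 2-sided permutation p = 0.175), which neither bears this out nor excludes it. All but 3 of these 15 genes were compressed, and the diet and the order of dissection stay open as untested.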

How the results depend on the processing

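The variable-only restriction, the meningeal covariate, the block on rat numbers and the tests on other splits of the rats were chosen after seeing the data. The count of 0 probe sets by limma held in every alternative fit, including the covariate and each rat left out (0 to 0). Alternative limma fits on all 31042 probe sets had 16 (common array median) to 1155 (without control rat 14) at an unadjusted p under 0.05, instead of 712. The fit on the 1223 variable probe sets had 7. Only the rank product differed, with 190 probe sets (115 higher, 75 lower). Of 100 splits of the rats, the real one included, 99 gave as many rank product calls as the real split (highest other 844), so chance was not excluded. For limma the splits decide nothing, since 100 of 100 reach a count of 0 by definition (highest other 5).

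The count of 0 lists became 7 with quantile normalization (6 higher, 1 lower), 10 with a common array median (6 higher, 4 lower), 1 with array weights, 1 with the block on rat numbers, 2 over variable probe sets alone and 0 to 2 without single rats: 2 without noodle-diet rat 1 and 1 without noodle-diet rat 7 or control rats 5, 8, 11 or 14. Here too 100 of 100 splits reach a count of 0 by definition (highest other 13), which decides nothing. The array medians spread over 0.0079, which is 48.4 times the median SD of compressed probe sets. Rescaling adds such differences between arrays to nearly all of them together, and the SD of the limma statistics over probe sets falls from 0.960 to 0.182 with a common median and to 0.448 with quantile normalization, so by construction nearly all statistics move together there. For single calls, and for the other settings, the cause was not tested. Every other setting run for the lists kept 0.

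Of 54 named genes and lists, 42 kept their direction in the fits that hold them; the fit on 1 probe set per gene was compared by its count only. With quantile normalization Pacs1 became -0.00055, Lrrc57 -5.6e-05, Sorl1 -0.00024, Npas2 -0.00029, Proser1 -4.1e-05 and Ghrh -0.00012. That setting moved the median difference over all probe sets from -4.6e-06 to -0.00023. The share of limma statistics above 0 fell from 48.0% to 23.4%. These compressed genes thus turned in the direction of a shift common to most probe sets. Whether that shift accounts for each gene was not tested. Oxt became -0.028 with 1 surrogate variable, and the cause was not tested. With the block it became -0.030, the same value as without control rat 11, which the block leaves without a partner. Leaving out single rats, Oxt ran from -0.178 to 0.440, Npy from -0.079 to 0.0064, Cartpt from -0.067 to 0.052, Hcrt from -0.074 to 0.249, Pmch from -0.0075 to 0.124, Gnrh1 from -0.085 to 0.190 and Ghrh from -1.6e-05 to 0.00015, since 1 rat of few moves these means. The labels name no pairs and give the groups no rat number in common, so the main comparison was unpaired. The block took sets of consecutive numbers (such as 1 and 2) that the labels do not name as pairs. Control rat 11 had no noodle-diet rat in its set, so it did not inform the diet difference there. Deviations correlated over 0.1 in 1 of 4 sets, and 1 of 4 noodle-diet rats correlated best with the control of its set. With the block limma called 0 probe sets, at 1029 unadjusted p under 0.05 instead of 712. The SD of the limma statistics was 1.27 with the block and 0.960 without. Limits on these results include the compression of 95.9% of probe sets and the number of arrays. Signal over background was not analysed here.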

Other observations

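The relations and tests below were chosen after the values had been seen. Thyrotropin transcripts varied strongly between rats on both diets. Tshb, the beta subunit, spanned 7.93 to 10.68, the alpha subunit gene Cga 10.49 to 11.97 and Nmu, the neuromedin U gene, 6.64 to 8.33. Over the 9 rats Tshb followed Cga (r = 0.948, exact permutation p = 0.00028, adjusted p = 0.00083; rho = 0.983, p = 5.0e-05) and Nmu (r = 0.842, exact permutation p = 0.0079, adjusted p = 0.0079; rho = 0.833, p = 0.0083). Without the 2 rats farthest from the median of Tshb the values were r = 0.914 and 0.713. Tshb and Cga belong to the list of anterior pituitary markers, fixed as neighbouring tissue. The pituitary hormone genes Gh1, Prl, Lhb and Fshb came from compressed probe sets, with means of 6.08, 5.82, 7.11 and 6.39. Whether they followed Tshb cannot be told, and the cause of the shared variation was not tested. Avp followed Oxt (r = 0.875, exact permutation p = 0.0031, adjusted p = 0.0046; rho = 0.733, p = 0.031; r = 0.750 without 2 rats). The adjustment covers these 3 relations alone and does not correct for their choice after the values had been seen. Correlations with the meningeal score and with Cd74 were also computed, and carry no p-value.

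Several genes stood at stepped levels, most of them shared by rats of both diets. Pxmp4, a peroxisomal membrane protein gene, lay at 7.79 to 7.81 in noodle-diet rat 1 and control rats 2 and 8, at 7.01 to 7.08 in noodle-diet rat 7 and control rats 11 and 14, and at 5.73 to 5.91 in noodle-diet rats 4 and 13 and control rat 5. Its second probe set put the same rats at 7.23 to 7.29, 6.86 to 7.01 and 6.28 to 6.41. Ccdc77 lay at 5.91 and 6.02 in noodle-diet rat 1 and control rat 2 and at 7.48 to 7.62 in noodle-diet rat 4 and control rats 5 and 14, with the others between, and Harbi1 spanned 6.70 to 7.50, Msh6 6.76 to 7.58 and Clcc1 7.36 to 7.89 in steps. Rnf138 stood high in control rats 8 and 14 alone, at 8.73 and 8.15, with the others at 7.16 to 7.31. A probe set of Lysmd4 lay higher on the noodle diet (difference 0.44) and further ones lower (-0.29 and -0.28), and none passed by limma. The suprachiasmatic peptide gene Vip, not picked as stepped, spanned 6.15 to 8.30 and followed the leading component described below (r = 0.799).

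The leading axis of variation followed meningeal markers. The leading component of the variable probe sets held 44.7% of their variance, did not separate the diets (exact 2-sided permutation p = 0.762) and was led by Ptgds (10.2 to 12.8), Slc13a4, Ogn, Slc6a20a and Slc22a6. A varying amount of meninges in the dissected tissue is a candidate explanation: the 15 markers of the list fixed in advance, 2 of which another list also holds and 8 of which stay above the median probe set even in their lowest rat, deviated together (mean pairwise r = 0.871, where 95% of random lists lay under 0.240). Oligodendrocyte markers did so as closely (mean pairwise r = 0.891). Shared deviation of a list therefore does not tell which cause moved it. The diet accounted for 0.0348% of the variance of the score, which argues against it. An array-wide difference in RNA quality or labelling stays open. Of the 57 control probe sets of the manufacturer, left out of the tests, 16 were variable. The largest range among these controls was 0.528 log2 units. Whether the controls followed the meningeal score was not tested, so they do not decide it. The score of 3 neurofilament genes varied with an SD only 0.170 times that of the meninges. Only these 3 of 15 measured neuron markers were variable. Compressed markers could not show such a spread, so the ratio does not decide the question. Of variable probe sets, 35.7% correlated negatively with the meningeal score, which does not decide it either, since how arrays were normalized is not given. The array medians ran in nearly the order of that score (rho = 0.983), but spread over only 0.739% of its spread. The median range of probe sets was 0.000518, less than the 0.0079 over which the array medians spread. The order of the medians therefore does not show a shift of most probe sets, and a shift hidden by compression is not excluded.

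RT1 genes, the major histocompatibility complex of the rat, also differed between animals. The class I gene RT1-CE16 ran from 5.86 to 7.88 and RT1-T24-3 from 6.06 to 7.48. A varying content of immune cells may lie behind class II (13.3% of 15 pairs of probe sets correlated negatively, median r with Cd74 0.808). That stays open, since RT1-Da, RT1-Db1 and Cd74 also followed the meningeal score. Cell content alone would not give the values of RT1-Bb, whose probe sets ran in opposite ways. In control rat 8 one stood highest at 7.70 and the other lowest at 6.04. In control rat 2 the first stood lowest at 5.30 and the other highest at 6.64. For class II the largest gap between neighbouring rats had a median share of the range of 0.240, where random lists had a median of 0.256. This gives no sign of sequence variants in class II and does not exclude them. For class I a varying content of immune cells is argued against, since 53.6% of 28 pairs correlated negatively. Diet accounted for a median of 5.36% of the variance in class I and 1.80% in class II, which argues against it. Segregating sequence variants cannot be told apart from other causes in class I, since the gaps between neighbouring rats (median share of the range 0.329) fell just short of the 95th percentile of random lists (0.331).

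Compressed values were not free of information. For 2911 genes with 2 compressed probe sets the median correlation between them over the 9 rats was 0.189, against 0.0083 for random pairs, and for 69 genes with 2 variable probe sets it was 0.863 against 0.0665. The real grouping by diet gave 712 probe sets at an unadjusted p under 0.05, fewer than each of the 99 other splits drawn, which gave 760 to 4005.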
